A study of Mus musculus with 9 samples.

How the data were processed

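Immortalized mouse podocytes, a conditionally growing kidney cell line, were kept per the labels' protocols at a permissive 33 °C and moved to 37 °C for 10 to 14 days to differentiate. Per the labels, the cells were then transfected with a control siRNA or with 1 of a pair of siRNAs against Usp40, and RNA was taken 48 h later. Per the labels, 1250 ng of RNA per sample went through poly(A) selection and a strand-specific library kit with 12 PCR cycles, and the libraries were sequenced in pairs of 36 bp reads, all in batch 1. The labels describe the 9 libraries, 3 per group, as biological replicates but do not say whether they came from separate cultures.

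The authors deposited 1 table with 25655 genes and every library. Per the submitters' processing notes, CLC Genomics Workbench 23.02 and DESeq2 were used with the mouse genome build GRCm39, and the role and version of DESeq2 are not given in the sources used here. The aligner's settings, the annotation release, whether counting used the strand of the reads, and the siRNA sequences are likewise not given in the sources used here. Per the file headers, the deposited columns hold total gene read counts, RPKM and TPM for each library. A further deposited column per library holds a signal, the authors' own scaled CPM, whose column sums run from 980798.55 to 1022194.8. The deposited table also holds the authors' comparisons of groups as a log2 fold change, a signed linear fold and p-values with their adjusted forms. In the authors' comparison of siRNA 1 with the control, 3530 genes hold an adjusted p-value of 0 beside a p-value above it, as do 3210 genes in their comparison of the siRNAs, and these zeros were treated as fillers and left out. Here the counts were tested, the authors' comparisons were set beside the results once, and RPKM, TPM and the scaled CPM columns were only inspected. All per-sample columns were mapped to a library by name, and each gene's symbol comes from the deposited table.

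The depth ranged from 9786270 to 13675426 gene counts per library, and 9483 genes had no count in any library. No library repeated another, since the chi-square per degree of freedom between replicates of a group lay between 3.26 and 19.1. Genes with too few counts were removed with edgeR's filterByExpr, which left 11800 genes and removed 13855. Scaling used TMM factors. The main test was edgeR's quasi-likelihood test with robust estimation on all 9 libraries, with the group as the only term, and the p-values were adjusted by Benjamini-Hochberg within a contrast. A gene was called at an adjusted p under 0.05. The biological coefficient of variation was 8.56%. The contrasts were siRNA 1 against the control siRNA, siRNA 2 against the control siRNA, the average of both siRNAs against the control siRNA, and siRNA 1 against siRNA 2. Standard errors of log2 fold changes were derived from the test's F value. These standard errors include the spread between libraries. CPM values use the TMM-scaled library size. No molecular identifiers are named in the labels, so reads from PCR copies are not independent molecules. Floors for counts of 0 cover counting error only.

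The gene lists were tested with limma's camera method with a preset correlation between genes of 0.01, and again with the correlation estimated from the data, with Benjamini-Hochberg adjustment over the 27 lists. Limma's fry test was planned beside it, with the same adjustment. The fry values given are of its directional form. It asks whether the members of a list change together in 1 direction, not whether they change more than other genes. A high value does not exclude that members change in both directions. The results of 1 list and of some single genes are not reported here. The other lists were slit diaphragm and podocyte identity, integrins and focal adhesion, extracellular matrix and fibrosis, intermediate filaments and mesenchymal markers, p53 targets, S phase, G2 and mitosis, interferon-stimulated genes, NF-kB targets with cytokines and chemokines, the unfolded protein and integrated stress responses, heat shock and cytosolic chaperones, NRF2 targets, sterol synthesis, glycolysis and hypoxia, oxidative phosphorylation, cytosolic ribosomal proteins, proteasome subunits, other ubiquitin-specific proteases, lysosome and autophagy, apoptosis regulators, YAP and TEAD targets, the siRNA processing machinery, and markers of mesangial, endothelial, parietal or tubular, and immune cells. The groups, tests, contrasts, lists and the rule for naming genes were fixed before the data were examined. By that rule Usp40, Hint1, Trp53, Nes, Cfl1 and Rhoa were always named. For the average contrast the rule took the 10 largest rises and the 10 largest falls among genes called in the average and in both single contrasts with 1 sign, with a mean of at least 2 CPM and with all siRNA libraries on the same side of all control libraries. For each other contrast it took the 6 largest rises and falls among called genes with a mean of at least 2 CPM and library values that did not overlap, and it passed over gene models named only by a code. From each list it took up to 4 called members with the smallest adjusted p in the average contrast or, where no member was called, the 2 members with the highest mean CPM.

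Because both single contrasts share the control libraries, unchanged groups were simulated 50 times against the same controls. Words of 7 bases were searched without a starting list in the annotated 3' UTR of each gene's canonical transcript, with GENCODE mouse release M 39, over the 11626 tested genes other than Usp40 that had at least 30 bases of it. Trends of the log2 fold changes with 3' UTR length, 3' UTR GC content and mean expression were first removed by regression, and each word's z compared genes with and without it, for words found in at least 30 genes. The genes were parted at random into groups of 5813, a word was searched in each part and tested in the other part, and extremes of z came from 100 shuffles of the fold changes. Of the deposited genes, 25494 matched that release by identifier, and all of these overlapped it in position. Transcript length and GC content also come from canonical transcripts. Trends with length or GC content were fitted with loess at a span of 0.5.

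The steps were tested on simulated data for siRNA 1 against the control siRNA with 11800 genes. There edgeR recovered 32% of 50 genes changed 1.3-fold, 64% of those changed 1.5-fold, 92% of those changed 2-fold and 96% of those changed 3-fold, with 14 false calls among 156. Other tools and settings were limma-voom, DESeq2, median-of-ratios and upper-quartile scaling, no filter and a stricter filter of 5 CPM in 3 libraries, each library left out in turn, a replicate block, only the groups compared, and both siRNA groups as 1 group. Settings added after the data were seen were removal of the GC or length trend, thinning to the smallest library, and leaving out genes that hold one of the 7-base words. Versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.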

Results

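RNA was measured in immortalized mouse podocytes, a cell line from the filtering epithelium of the kidney, 48 h after transfection with a control siRNA, with siRNA 1 against Usp40 or with siRNA 2 against Usp40. Each group held 3 libraries, labelled as biological replicates, and the labels do not state separate cultures, so the p-values measure the spread between these libraries. The control libraries held 11898321, 10784049 and 12390673 gene counts. The siRNA 1 libraries held 11895046, 11227198 and 11777961, and the siRNA 2 libraries 9786270, 12653723 and 13675426. Of the podocyte identity genes fixed before the data were examined, 24 of 35 had enough counts to be tested. Over all 9 libraries together, the slit diaphragm gene Nphs1 had 2 counts, the transcription factors Wt1 and Lmx1b had 40 and 13, and Ptpro and Tcf21 had 0, which allows up to about 3 counts over all of them.

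The targeted transcript was examined first. Usp40 (ENSMUSG00000005501, GRCm39 chromosome 1, 87872841 to 87936273, minus strand) encodes a deubiquitinating enzyme and was lower in every siRNA library than in every control library. It had 371, 365 and 503 counts in the control libraries, 173, 174 and 196 with siRNA 1, and 190, 222 and 295 with siRNA 2. Its level was 35.5 ± 4.79 CPM (SD, n = 3) in controls, 15.7 ± 1.09 CPM (SD, n = 3) with siRNA 1 and 19.2 ± 1.96 CPM (SD, n = 3) with siRNA 2. Usp40 fell to 44.2% of control with siRNA 1 (log2 fold change -1.18, SE 0.115, edgeR adjusted p = 0.000727) and to 54.2% with siRNA 2 (log2 fold change -0.88, SE 0.112, edgeR adjusted p = 0.00047). The difference between the siRNAs did not pass the test (log2 difference -0.29, SE 0.121, edgeR adjusted p = 0.185). The annotated end of Usp40 overlaps Dgkd on the opposite strand by 62 bp, and whether counting used the strand is not given in the sources used here. Among proteins earlier tied to USP40, the transcripts of Hint1, Trp53 and Nes had average log2 fold changes of -0.08, -0.01 and 0.26 (edgeR adjusted p = 0.663, 0.933 and 0.283). The actin regulators Cfl1 and Rhoa had -0.19 and -0.26 (edgeR adjusted p = 0.0953 and 0.0615).

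**Figure D1:**
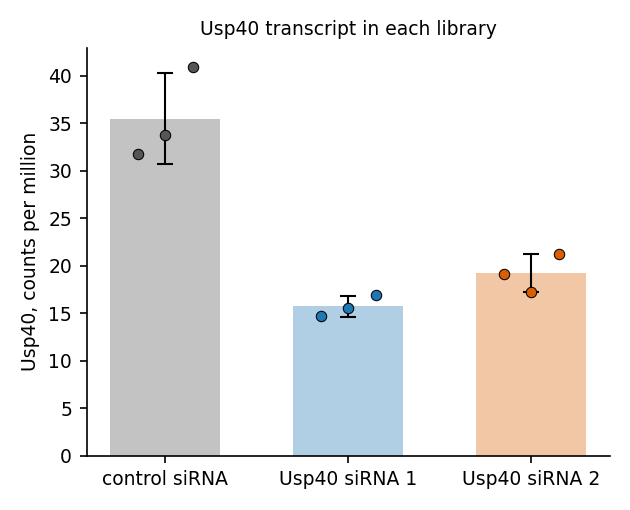
Usp40 transcript level in CPM for the control siRNA, siRNA 1 and siRNA 2, where bars are means of 3 libraries, error bars the SD and points single libraries. The means are 35.5, 15.7 and 19.2 CPM.

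The average of the siRNA effects was tested against the control, and a call in it can come from 1 siRNA alone. Of its 864 calls, 88 were also called with both siRNAs, 685 with siRNA 2 alone, 60 with siRNA 1 alone and 31 with neither, and 39 had opposite signs with the siRNAs. The histone gene H2bc4 (ENSMUSG00000018102, chromosome 13, 23868182 to 23876891) rose from 6.82 ± 1.26 CPM (SD, n = 3) in controls to 13.7 ± 0.609 with siRNA 1 and 53 ± 11.2 with siRNA 2 (average log2 fold change 1.97, SE 0.163, edgeR adjusted p = 0.000242). Pard3b (ENSMUSG00000052062, chromosome 1, 61677983 to 62681443), a cell polarity gene, rose from 7.43 ± 0.343 CPM (SD, n = 3) to 14.8 ± 1.32 and 20.9 ± 2.07 (average log2 fold change 1.24, SE 0.103, edgeR adjusted p = 0.000242). The methionine sulfoxide reductase gene Msrb3 (0.69, SE 0.0646), the Rab GTPase-activating gene Tbc1d9 (0.75, SE 0.117), Rbm18 (0.68, SE 0.0825) and the lysophosphatidylcholine acyltransferase gene Lpcat1 (0.64, SE 0.0608) also rose on the log2 scale. By the rule for genes called with both siRNAs, the falls after Usp40 were in Tmem64 (-0.83, SE 0.0847), Septin2_1 (-0.80, SE 0.11), the endoplasmic reticulum oxidase gene Ero1a (-0.77, SE 0.0655) and the calcium-binding gene S100a6 (-0.67, SE 0.0968). Akirin1 (-0.65), Fam118a (-0.59), the chromatin remodeling gene Pbrm1 (-0.56) and the R-spondin receptor gene Lgr4 (-0.55) fell as well. Over 11800 tested genes, 359 rose and 505 fell in the average contrast at an edgeR adjusted p under 0.05. Reads of H2bc4 can be shared with near-identical copies, and after poly(A) selection its values do not cover transcripts without a poly(A) tail. Septin2_1 (4115 counts) overlaps another entry of the same symbol, Septin2_2 (30801 counts), on the same strand over 30741 bp. Rbm18 and Pbrm1 overlap counted genes on the other strand. The values of H2bc4, Septin2_1, Rbm18 and Pbrm1 are thus uncertain. The call count of 864 was 174 without control replicate 2, 1478 without control replicate 3, 496 without siRNA 1 replicate 3, and 408, 415 and 351 without siRNA 2 replicates 1, 2 and 3. With both siRNA groups fitted as 1 group it was 54.

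Other genes named by the same rule lost their calls when a library was left out, which also leaves fewer libraries for the test. The glutamate transporter gene Slc1a2 rose in the average (log2 fold change 1.08, SE 0.239, edgeR adjusted p = 0.0219), but lost its call without control replicate 1 or 2 (0.0527 and 0.1) and without siRNA 2 replicate 2 or 3 (0.0512 and 0.0598). Tmem143 (0.79), Sox8 (0.67) and Adgra1 (0.66) rose and Zbtb34 (-0.56) fell. Their edgeR adjusted p without control replicate 2 became 0.0512, 0.0506, 0.0713 and 0.0625.

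Gene lists were then compared in the average contrast, with counts of members that passed over all genes tested and, in turn, adjusted over the list alone. Of the 38 proteasome subunit genes, 5 fell (25 adjusted over the list alone): Psma1 (-0.47, SE 0.0796), Psmb5 (-0.31), Psma7 (-0.27), Psmc4 (-0.20) and, chosen after its values were seen, Psmd6 (-0.29). The list was lower by camera (median log2 fold change -0.18, adjusted p = 1.22e-08). Its adjusted p was 0.666 with an estimated correlation. Of 40 genes of the unfolded protein and integrated stress responses, 10 fell (13 adjusted over the list alone), among them Ero1a (-0.77) and the co-chaperone gene Dnajc3 (-0.33). That list was lower by camera (median -0.12, adjusted p = 4.07e-06), with an adjusted p of 0.60 with an estimated correlation. Of 51 G2 and mitosis genes, 9 fell (16 adjusted over the list alone), including Birc5 (-0.60) and Pbk (-0.44), with a camera adjusted p of 0.000191 that was 0.766 with an estimated correlation. Of 39 interferon-stimulated genes, 3 rose (3 adjusted over the list alone), namely Oasl2 (0.53), Irf7 (0.45) and Oas1a (0.53), with a camera adjusted p of 0.00599 that was 0.60 with an estimated correlation. Of 45 oxidative phosphorylation genes, 2 fell (2 adjusted over the list alone), Cox5a (-0.90) and Cycs (-0.44), with a camera adjusted p of 7.98e-05 that was 0.766 with an estimated correlation and 0.391 with the preset one without control replicate 1. By fry the adjusted p of these lists, in the order given, were 0.0727, 0.00929, 0.102, 0.0277 and 0.334. Without control replicate 2, the edgeR adjusted p of Dnajc3, Oasl2 and Cycs became 0.0518, 0.0567 and 0.0889. Cox5a had log2 fold changes of -0.24 with siRNA 1 and -1.56 with siRNA 2, and Dnajc3 -0.10 and -0.57, each called with siRNA 2 alone. Irf7 overlaps a counted gene on the other strand with more counts, so its value is uncertain. The calls of Psmb5, Psma7, Psmc4, Irf7 and Oas1a ended without control replicate 2 and without at least 5 other libraries each, at edgeR adjusted p up to 0.0975, 0.127, 0.113, 0.144 and 0.154.

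Lists of cell structure were not called by camera in the average contrast. Of 24 tested podocyte identity genes, 2 rose (2 adjusted over the list alone), the ephrin gene Efnb1 (0.35, edgeR adjusted p = 0.0131) and the actin-associated podocyte gene Synpo (0.29, edgeR adjusted p = 0.0349), and the camera adjusted p was 0.146. Without control replicate 2 the edgeR adjusted p was 0.0648 for Efnb1 and 0.119 for Synpo, and Synpo also lost its call without control replicate 1, siRNA 1 replicates 2 and 3 or any siRNA 2 replicate, at 0.0538 to 0.091. Of 29 integrin and focal adhesion genes, 1 rose and 2 fell (2 and 2 adjusted over the list alone), Tns1 (0.48) rising and Fermt2 (-0.35) and Itgav (-0.45) falling. With siRNA 1 Fermt2 and Itgav had -0.07 and 0.03, and with siRNA 2 alone they were called, at -0.63 and -0.93. The edgeR adjusted p without control replicate 2 was 0.0648 for Itgav and 0.136 for Tns1, which also lost its call without control replicate 1, siRNA 1 replicates 2 and 3 or any siRNA 2 replicate. Of 37 extracellular matrix genes, 4 rose and 3 fell (5 and 4 adjusted over the list alone), Tnc (0.51), Tgm2 (0.30), Col6a1 (0.29) and Timp2 (0.24) rising and Ccn2 (-0.33), Tgfb2 (-0.32) and Thbs1 (-0.32) falling, with Timp2 and Thbs1 chosen after their values were seen. All of these were called with siRNA 2 alone, Ccn2 at -0.61 against -0.05 with siRNA 1, and Tgm2 overlaps a counted gene on the other strand, so its value is uncertain. Without control replicate 2 the edgeR adjusted p was 0.0905 for Tnc, 0.0551 for Tgm2, 0.119 for Col6a1, 0.136 for Ccn2 and 0.0937 for Tgfb2. Of 18 intermediate filament and mesenchymal genes, Cd44 (0.28) rose and Krt7 (-0.45) fell (1 and 1 adjusted over the list alone), and their edgeR adjusted p was 0.132 and 0.109 without control replicate 2. Of 22 YAP and TEAD targets, 2 fell (5 fell and 2 rose adjusted over the list alone), Tgfb2 and Ccn2. Besides control replicate 2, the calls of Col6a1, Ccn2, Tgfb2, Cd44 and Krt7 ended without other libraries, siRNA 2 replicate 3 in each case, at edgeR adjusted p of 0.0611, 0.0639, 0.0598, 0.0752 and 0.118. The YAP list's median was positive while camera's direction was down.

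Further lists of growth, death, metabolism and other cell types, given next, were not called by camera in the average contrast. Of 46 S phase genes, 1 rose and 3 fell (4 and 5 adjusted over the list alone), the histone mRNA-binding gene Slbp (-0.55), the helicase gene Mcm4 (-0.44) and Dbf4 (-0.35) falling and the ligase gene Lig1 (0.21) rising. Of 34 p53 targets, 2 fell (2 adjusted over the list alone), Zmat3 (-0.52) and Eda2r (-0.27). Slbp, Mcm4, Zmat3 and Eda2r were called with siRNA 2 alone, at -1.05, -0.93, -0.95 and -0.50, against -0.05, 0.05, -0.08 and -0.04 with siRNA 1. Of 31 apoptosis regulators, 1 rose and 3 fell (1 and 3 adjusted over the list alone): Bcl2l11 (0.23) rose, and Birc5 (-0.60) and Cycs (-0.44) were among those that fell. Of 34 NRF2 targets, 2 rose and 1 fell (2 and 2 adjusted over the list alone): the ferritin gene Fth1 at 0.49, the glutathione reductase gene Gsr at 0.26 and the peroxiredoxin gene Prdx6 at -0.40. Of 41 lysosome and autophagy genes, 2 rose and 5 fell (3 and 6 adjusted over the list alone), the saposin precursor gene Psap (-0.49), Gla (-0.31), Becn1 (-0.25), Atg5 (-0.31) and Neu1 (-0.29) falling and Optn (0.29) and Wipi1 (0.35) rising, with Atg5, Neu1 and Wipi1 chosen after their values were seen. Psap had 0.03 with siRNA 1 and -1.0 with siRNA 2. That list's median was positive while camera's direction was down. Of 34 sterol synthesis genes, 1 fell (1 adjusted over the list alone), Msmo1 (-0.38). Of 24 NF-kB targets, 1 rose (1 adjusted over the list alone), the complement gene C3 (0.87). Of 49 other ubiquitin-specific proteases, 2 rose (2 adjusted over the list alone), Usp30 (0.40) and Usp25 (0.25), and of 14 genes of the siRNA processing machinery 2 rose (3 rose and 1 fell adjusted over the list alone), Tnrc6a (0.60) and Tlr3 (0.30). Usp30 overlaps counted genes on the other strand, so its value is uncertain. Without control replicate 2 the edgeR adjusted p was 0.101 for Dbf4, 0.0928 for Lig1, 0.0981 for Eda2r, 0.104 for Bcl2l11, 0.0889 for Cycs, 0.117 for Gsr, 0.0668 for Psap, 0.0827 for Gla, 0.11 for Becn1, 0.0886 for Optn, 0.0844 for Msmo1, 0.0619 for Usp25 and 0.0995 for Tlr3. All of these except Cycs, Psap, Gla and Msmo1 also lost their calls without siRNA 2 replicate 1, at edgeR adjusted p of 0.0519 to 0.091. Marker lists of other cell types held Flt1 (0.68), which rose among 5 endothelial genes (1 adjusted over the list alone), and Krt7, which fell among 9 parietal and tubular genes (2 adjusted over the list alone).

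In 5 lists no member passed in the average contrast by edgeR or by limma-voom. At an unadjusted p under 0.05 edgeR had 1 higher and 4 lower among 23 heat shock genes, 2 higher and 4 lower among 30 glycolysis genes, 3 higher and 1 lower among 10 mesangial markers, and 1 higher and 1 lower among 4 immune markers. Among 71 cytosolic ribosomal protein genes edgeR had 0 at an unadjusted p under 0.05. DESeq2 called 1 glycolysis gene higher and 2 lower, and called 0 in the other lists. Adjusted over the list alone, 1 immune marker was higher and 1 lower. Camera adjusted p of lists not called in the average contrast ran from 0.10 for ribosomal proteins to 0.964 for glycolysis.

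The changes with each siRNA were compared with one another. Of the genes that rose with siRNA 1, 56 also rose with siRNA 2, among them H2bc4, Pard3b and Msrb3, and 32 genes fell with both, among them Usp40, Ero1a and S100a6. Lists drawn independently would share 5.78 and 10.2 genes. Hook1, an adaptor gene of microtubule transport, fell with siRNA 1 (-0.72, SE 0.0871, edgeR adjusted p = 0.00217) and rose with siRNA 2 (0.27, SE 0.083, edgeR adjusted p = 0.0433), as did Topbp1, which was chosen after its values were seen (-0.52, SE 0.0806 and 0.28, SE 0.0794). The count of 56 was 11 without control replicate 2, 17 and 10 without siRNA 1 replicates 2 and 3, and 22, 25 and 22 without siRNA 2 replicates 1, 2 and 3. The count of 32 was 3 and 51 without control replicates 2 and 3, 20, 12 and 4 without siRNA 1 replicates 1, 2 and 3, and 17, 15 and 12 without siRNA 2 replicates 1, 2 and 3. Across genes, which are not independent replicates, the fold changes had a Pearson r of 0.560 and a Spearman correlation of 0.577. In 50 simulations of unchanged groups against the same controls the means were 0.508 (0.429 to 0.608) and 0.470 (0.45 to 0.491), so r lay inside its simulated range and the Spearman correlation above its own. With a library left out r ran from 0.347 to 0.706. The covariance was 0.0462 against a simulated 0.0158 (0.0131 to 0.0221), and the same sign was seen in 72.6% of genes against 66.8% (65.6% to 67.9%). The simulations gave 0 shared calls. Lists of equal length taken from them shared 41.9 genes (31 to 50) among rises and 60.1 (48 to 72) among falls. The 56 shared rises lay above that range and the 32 shared falls below theirs. The simulated lists held the top-ranked genes of data without an effect, while the real lists also hold genes changed with 1 siRNA alone. Their overlaps are thus not compared like for like. The simulations drew each gene independently, while deviations of the real libraries from their group means shared a main axis. That axis held 53.7% of their variance, and its gene weights followed transcript length (Spearman correlation 0.605). The simulated ranges may thus be too narrow, so values outside them do not show agreement beyond the shared controls. The 3 control libraries were not divided between the siRNAs, and sharing them may account for part of the agreement.

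**Figure D2:**
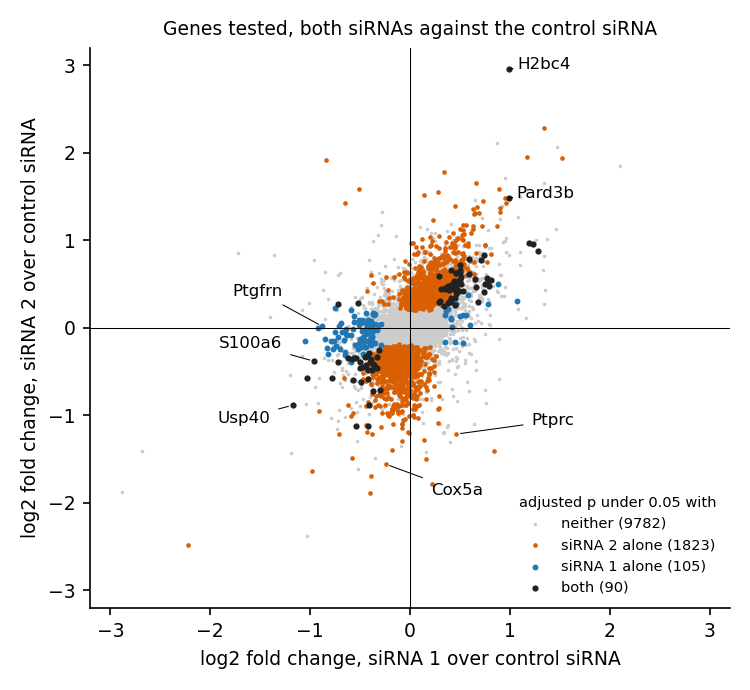
Log2 fold change over the control siRNA with siRNA 1 (horizontal) and siRNA 2 (vertical), 1 point per tested gene, with 5 genes outside the axes. By edgeR adjusted p under 0.05, 9782 genes passed with neither siRNA, 105 with siRNA 1 alone, 1823 with siRNA 2 alone and 90 with both.

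With siRNA 1 alone against the control, 74 genes rose and 121 fell at an edgeR adjusted p under 0.05. Lpcat1 rose 1.73-fold (log2 fold change 0.79, SE 0.0686, edgeR adjusted p = 0.000727), Rbm18 rose 1.76-fold and Pard3b 1.98-fold. S100a6 (ENSMUSG00000001025, chromosome 3, 90520189 to 90531488) fell from 2228 ± 232 CPM (SD, n = 3) to 1143 ± 174 (log2 fold change -0.96, SE 0.115, edgeR adjusted p = 0.00217). Septin2_1 (-1.03, SE 0.132) and the immunoglobulin superfamily gene Ptgfrn (-0.88, SE 0.113) fell, Ptgfrn from 222 ± 38.6 CPM (SD, n = 3) to 121 ± 7.35. H2bc4 (0.99), Slc1a2 (1.28) and Exoc3l4 (0.88) rose, and Kbtbd8 (-1.05) and the metalloproteinase inhibitor gene Reck (-0.92) fell. These calls ended when a library was left out, the edgeR adjusted p without control replicate 2 being 0.128 for H2bc4, 0.159 for Slc1a2, 0.162 for Exoc3l4, 0.139 for Reck and 0.0953 for Kbtbd8, and without siRNA 1 replicate 3 being 0.116, 0.0573, 0.101, 0.137 and 0.196. The call count of 195 was 49 without control replicate 2, 76 and 36 without siRNA 1 replicates 2 and 3, and 116, 117 and 110 without siRNA 2 replicates 1, 2 and 3.

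Among gene lists with siRNA 1, 15 of the 39 interferon-stimulated genes were higher at an unadjusted p under 0.05, and Oasl2 rose (0.78, edgeR adjusted p = 0.00729), with 3 adjusted over the list alone. The list was higher by camera (median log2 fold change 0.23, adjusted p = 8.38e-08), and its adjusted p was 0.117 with an estimated correlation. No list call of camera in any of the contrasts held with an estimated correlation. Fry, which asks a different question, passed some of these lists. With siRNA 1 its adjusted p was 0.0141 for interferon-stimulated genes and 0.0493 for the stress response list. It was 0.103 for NRF2 targets and for G2 and mitosis, 0.320 for proteasome subunits and 0.608 for oxidative phosphorylation. The NRF2 targets Fth1 (0.68), Hmox1 (0.53, SE 0.0809) and Gsr (0.41) rose and Prdx6 (-0.40) fell among 34 (3 and 1 adjusted over the list alone), with Hmox1 chosen after its values were seen. Camera gave that list an adjusted p of 0.00222, 0.435 with an estimated correlation, and up to 0.102 with the preset one without control replicate 3 or siRNA 1 replicate 3. Of the G2 and mitosis genes 1 fell (11 adjusted over the list alone), Spc24 (-0.46, SE 0.0916), chosen after its values were seen, with a camera adjusted p of 1.45e-08 that was 0.435 with an estimated correlation. Ero1a (-0.42) and Trib3 (-0.56, SE 0.112), the latter chosen after its values were seen, fell in the stress response list (2 adjusted over the list alone, camera adjusted p = 3.61e-05, and 0.435 with an estimated correlation). Psma1 (-0.58) fell among proteasome genes (1 adjusted over the list alone), with a camera adjusted p of 6.4e-05 that was 0.690 with an estimated correlation and 0.0672 with the preset one without control replicate 1. The oxidative phosphorylation list had a median of -0.08 and a camera adjusted p of 0.0145, which was 0.762 with an estimated correlation. Without control replicate 1 its median was 0.0234 and its adjusted p 0.668, and without siRNA 1 replicate 2 they were 0.00618 and 0.795.

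With siRNA 2 against the control, 922 genes rose and 991 fell at an edgeR adjusted p under 0.05. In poly(A)-selected RNA H2bc4 rose 7.76-fold (log2 fold change 2.96, SE 0.17, edgeR adjusted p = 9.74e-06) and Pard3b 2.80-fold. The endothelial lipase gene Lipg rose 2.56-fold (1.36, SE 0.14) and the calcium channel subunit gene Cacng4 3.15-fold (1.66, SE 0.219), both from low levels of 3.87 and 1.09 CPM in controls. Cox5a (ENSMUSG00000000088, chromosome 9, 57428557 to 57439709), a subunit gene of cytochrome c oxidase, fell from 170 ± 27.7 CPM (SD, n = 3) to 57.9 ± 6.82 (log2 fold change -1.56, SE 0.125, edgeR adjusted p = 4.07e-05). Rcn2 (-1.40, SE 0.12), the mitochondrial outer membrane channel gene Vdac1 (-1.29, SE 0.0968), Mfsd4b1 (-1.69, SE 0.301) and the leukocyte phosphatase gene Ptprc (-1.21, SE 0.241) fell as well, Vdac1 from 441 ± 43.3 CPM (SD, n = 3) to 180 ± 17.5. Psme2b (2.28) and the proton channel gene Hvcn1 (1.52) rose and Dpysl2 (-1.21) fell, with calls that ended at edgeR adjusted p of 0.0756 and 0.0611 without siRNA 2 replicates 3 and 1 for the first pair and 0.119 without control replicate 1 for Dpysl2. Psme2b overlaps counted genes on its own strand and Hvcn1 a gene on the other, so both are uncertain. The call count of 1913 was 1001 without control replicate 2, and 862, 947 and 636 without siRNA 2 replicates 1, 2 and 3.

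Among lists with siRNA 2, 22 of 38 proteasome subunit genes fell (30 adjusted over the list alone), among them Psmb5 (-0.46) and Psma1 (-0.36). The list had a median log2 fold change of -0.27 and a camera adjusted p of 1.25e-08, and its adjusted p was 0.595 with an estimated correlation. Of 34 NRF2 targets, 11 fell and 1 rose (20 and 1 adjusted over the list alone), Prdx6 at -0.39 and Fth1 at 0.30, with a camera adjusted p of 3.81e-06 that was 0.269 with an estimated correlation. Of 40 stress response genes, 12 fell (14 fell and 1 rose adjusted over the list alone), including Ero1a (-1.12) and Dnajc3 (-0.57), with a camera adjusted p of 4.36e-05 that was 0.423 with an estimated correlation. Of 45 oxidative phosphorylation genes 3 fell (3 adjusted over the list alone), Cox5a, Cycs (-0.53) and Uqcrq (-0.38). Of 71 ribosomal protein genes 1 fell, Rpl38 (-0.31), while edgeR adjusted over the list alone gave 0, with 17 lower at an unadjusted p under 0.05, 5 by DESeq2 and 1 by limma-voom. Uqcrq and Rpl38 were chosen after their values were seen. Both of these lists had a median of -0.20 and a camera adjusted p of 3.79e-05, which was 0.744 with an estimated correlation, and with a library left out their medians ran from -0.27 to -0.09 and from -0.27 to -0.08. Both were nearest 0 without control replicate 1, where the adjusted p were 0.019 and 0.0823. Fry gave adjusted p of 0.0301 for proteasome subunits and 0.00258 for NRF2 targets and for the stress response list. It gave 0.244 for oxidative phosphorylation and 0.283 for ribosomal proteins. Among lists without a camera call, 8 of 22 YAP and TEAD targets (6 higher and 9 lower adjusted over the list alone), 5 of 30 glycolysis genes (6 adjusted over the list alone) and 4 of 34 p53 targets (4 adjusted over the list alone) fell and 0 rose by edgeR. DESeq2 called 3 YAP and TEAD targets and 1 glycolysis gene higher, and limma-voom 1 YAP and TEAD target. Others held changes in both directions, such as 7 higher and 5 lower of 37 extracellular matrix genes (9 and 5 adjusted over the list alone) and 11 higher and 3 lower of 46 S phase genes (13 and 5 adjusted over the list alone).

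**Figure D3:**
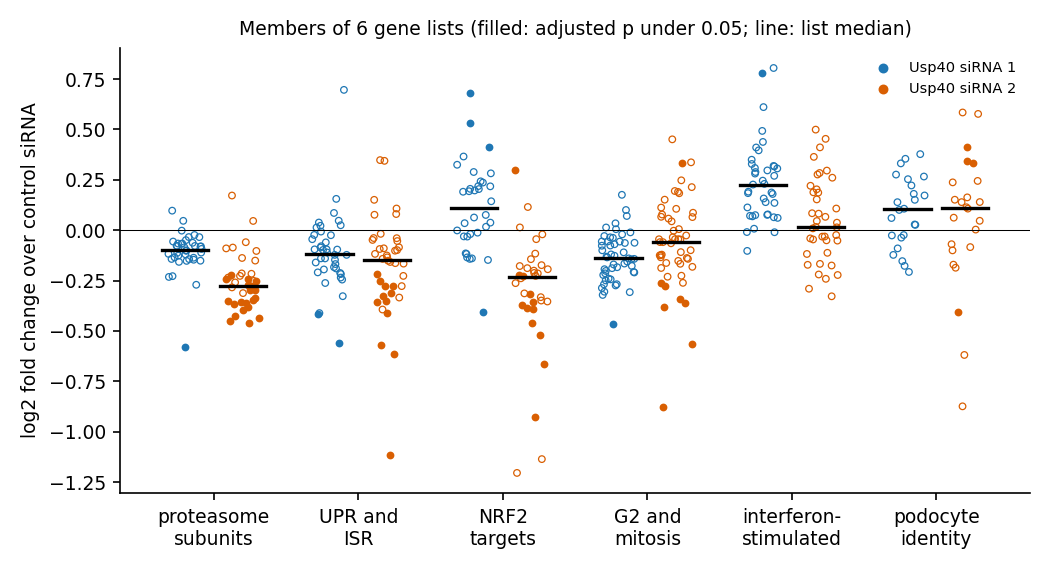
Log2 fold changes over the control siRNA of the tested members of 6 gene lists with siRNA 1 and siRNA 2, where each point is a gene, filled points have an edgeR adjusted p under 0.05 and lines are list medians. The proteasome medians are -0.10 and -0.27, and the interferon medians 0.23 and 0.02.

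Transcript length differed along the same axis as some of these lists. The median canonical transcript was 1096 bases for ribosomal proteins, 1445 for oxidative phosphorylation, 1701.5 for proteasome subunits, 2508 for the stress response list, 2642 for NRF2 targets and 2656 for interferon-stimulated genes, against 3491 for all tested genes. The slope of log2 CPM per doubling of length was -0.155, -0.0151 and 0.0161 in the control libraries, -0.0722, 0.0837 and -0.0327 with siRNA 1, and 0.0606, 0.0246 and 0.0900 with siRNA 2. By a two-sided exact permutation test the slopes with siRNA 2 and the control differed at p = 0.1, the smallest p that 3 against 3 libraries allow. With each library's length trend removed, the camera adjusted p with siRNA 2 was 9.53e-06 for proteasome subunits, 0.000224 for NRF2 targets, 0.0499 for oxidative phosphorylation and 0.643 for ribosomal proteins. Their medians went from -0.27 to -0.19, from -0.23 to -0.22, from -0.20 to -0.06 and from -0.20 to -0.02. With siRNA 1 the oxidative phosphorylation call ended (median -0.05, adjusted p = 0.153) and the ribosomal list was called higher (median 0.09, adjusted p = 2.77e-06). In the average the oxidative phosphorylation median went from -0.14 to -0.05 (adjusted p = 0.0448). Among named genes the average calls of Psma7 (log2 fold change -0.16, edgeR adjusted p = 0.0678), Psmc4 (-0.11, 0.197) and Cd44 (0.21, 0.0879) and the siRNA 2 call of Dpysl2 (-1.26, 0.0668) ended with the length trend removed.

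The siRNAs were then tested against each other, a comparison in which the control cancels. At an edgeR adjusted p under 0.05, 501 genes were higher and 294 lower with siRNA 1 than with siRNA 2. Cox5a (log2 difference 1.31, SE 0.125), Rcn2 (1.22, SE 0.12) and Ptprc (1.68, SE 0.229) were higher with siRNA 1, and H2bc4 (-1.96, SE 0.155), Hook1 (-1.0, SE 0.0862) and Islr (-1.0, SE 0.194) were lower. Islr overlaps a counted gene on its own strand and is uncertain. Of 34 NRF2 targets, 16 were higher with siRNA 1 than with siRNA 2 (23 adjusted over the list alone), with a median log2 difference of 0.33 and a camera adjusted p of 3.94e-17. Hmox1 (0.70, SE 0.0812) and Gsta4 (0.71), chosen after their values were seen, were among them, and the list's adjusted p was 0.0505 with an estimated correlation. Of 24 NF-kB targets, 4 were higher, Ccl2 (0.83), Ccl5 (1.11), Cxcl1 (0.81) and Ptgs2 (0.92), all chosen after their values were seen, and C3 (-0.62) was lower (10 and 1 adjusted over the list alone), with a camera adjusted p of 0.000999 that was 0.0927 with an estimated correlation. Camera also called the ribosomal (2.38e-10), proteasome (0.000423), interferon (0.00494), oxidative phosphorylation (0.00555), glycolysis (0.0264) and p53 (0.0272) lists higher in adjusted p, and with an estimated correlation their adjusted p were 0.711, 0.711, 0.268, 0.833, 0.711 and 0.221. By fry they were 0.168, 0.151, 0.0126, 0.413, 0.0613 and 0.00455, and for the NRF2 and NF-kB lists 0.000943 and 0.00404. The glycolysis call ended without siRNA 1 replicate 1 or siRNA 2 replicate 3 (up to 0.0992), and the oxidative phosphorylation call without siRNA 1 replicate 1 (0.297). With the length trend removed, the oxidative phosphorylation call (median 0.13 to 0.02, adjusted p = 0.238) and the p53 call (0.066) ended and the ribosomal median went from 0.22 to 0.11. S phase (0.0333) and G2 and mitosis (0.0229) were then called lower and YAP and TEAD targets (0.0229) higher. The same lists were called with the GC trend removed (0.0489, 0.0222 and 0.0312), as was G2 and mitosis with a replicate block (0.0312). In other contrasts, GC removal called the ribosomal list lower in the average (0.0458), and a replicate block called the siRNA processing list higher with siRNA 1 (0.0438). Without genes holding a 7-base word, given next, the p53 adjusted p was 0.337 with 26 genes left and a median of 0.06 against 0.08, which does not show that the words carry the difference. There S phase (0.000723) and G2 and mitosis (0.00838) were called lower and YAP and TEAD targets (0.0241) higher. Without those genes camera also called the S phase list (0.00747) and the extracellular matrix list (0.033) higher with siRNA 2, and the latter higher in the average (0.0296). In this setting the genes left the lists but stayed among the other genes that camera compares with. Genes with a word of siRNA 2 were lower with siRNA 2. Lists without such genes can thus move up with siRNA 2, and down in the difference, by construction. The list calls that appear only in this setting are therefore not read as changes. The call count of 795 was 1335 without control replicate 1, 495 and 375 without siRNA 1 replicates 1 and 3, and 436, 403 and 361 without siRNA 2 replicates 1, 2 and 3.

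Words of 7 bases in annotated 3' UTRs were compared with the fold changes. Genes holding GTTATAC, 594 in all, were lower with siRNA 1 by a log2 difference of -0.147 (z = -14.1, against a lowest z of -6.97 in 100 shuffles), and had a z of -1.79 with siRNA 2. Genes holding GACTTAA, 1316 in all, were lower with siRNA 2 by -0.157 (z = -16.9, lowest shuffled z -4.69), and had a z of -1.11 with siRNA 1. GTTATAC lies in exon 7 of 32 of Usp40, within the coding sequence, at chromosome 1, 87923473 to 87923479. GACTTAA lies in coding exon 13, at 87909781 to 87909787. GACGTAA, which is not in the Usp40 transcript, marked genes that were higher in the average contrast (z = 7.90, highest shuffled z 6.64). Its z with siRNA 1 alone was 7.78, below a highest shuffled z of 9.65, and with siRNA 2 alone 6.33, above a highest shuffled z of 5.66. In searches for rises with a single siRNA, the words found in the first part, GCAACGA and TTGCCCG, had a z of 0.333 and 0.649 in the other part. Those from the second part, AGACGTA and TGACGTA, had 4.01 and 3.73. Among the called genes of the parts not searched, 34 of 59 and 41 of 60 genes that fell with siRNA 1 held its word, as did 185 of 513 and 145 of 468 that fell with siRNA 2. Of all genes called lower, 75 of 121 with siRNA 1 and 414 of 991 with siRNA 2 held a word of that siRNA, GACTTAA or GGACTTA for siRNA 2, against 5.03% and 15.1% of tested genes. Among the falls named above, Cox5a, Rcn2, Vdac1, Dpysl2, Ero1a, Akirin1, Psap, Slbp, Mcm4, Itgav, Fermt2, Zmat3, Birc5, Pbk, Cycs, Dnajc3, Neu1 and Atg5 hold a word of siRNA 2. S100a6, Ptgfrn, Hook1 and Topbp1 hold that of siRNA 1, and Tmem64, Fam118a, Pbrm1, Lgr4 and Eda2r hold words of both. Of the genes called higher with both siRNAs, 8 of 31 and 6 of 25 in the parts not searched held the word found, GACGTAA or AGACGTA, against 1.49% and 1.5% of other genes there. With words chosen over all genes, 27 of 56 held one of the GACGTAA group, against 4.09% of tested genes, H2bc4, Pard3b, Msrb3 and Lpcat1 among them. Other rises named above, such as Oasl2 and Lipg, hold one of that group too, and Oasl2 also holds a word of siRNA 2. Without genes holding a word, 0 of 36 interferon-stimulated genes were called with siRNA 1, at a median log2 fold change of 0.19. Of the genes called lower with both, 12 of 32 had none of these words found, Usp40 and Septin2_1 among them, where 1 of the 12 had no 3' UTR to search. Close words, such as TGACTTA with siRNA 2 (z = -10.8) and TTATACA with siRNA 1 (z = -7.19), also lay beyond the lowest shuffled z. They were not counted here.

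**Figure D4:**
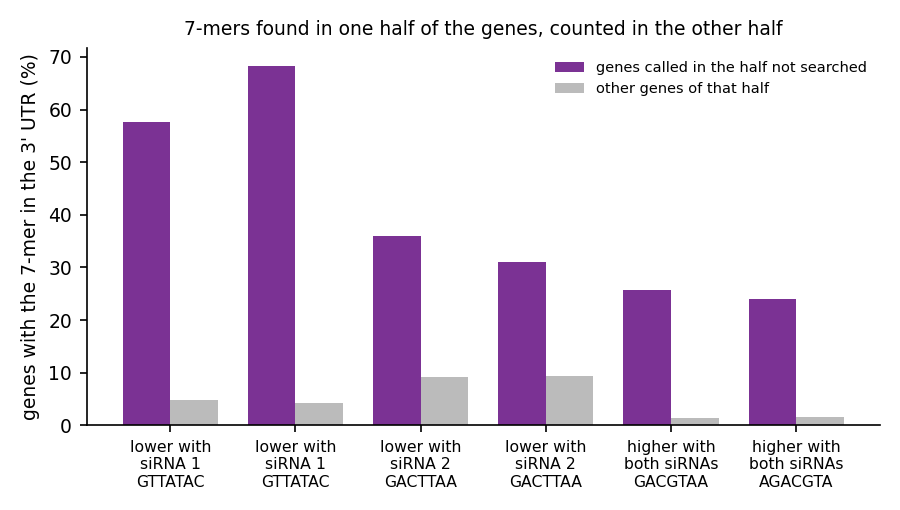
Percentage of called genes and of other genes that hold the word of 7 bases found in the other part of the genes, as 6 pairs of bars. With siRNA 1 the called genes are at 57.6% and 68.3% and the other genes at 4.74% and 4.28%.

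In the authors' deposited table, 282 genes had an adjusted p-value under 0.05 for siRNA 1 against the control, 2037 for siRNA 2 and 992 between the siRNAs. Of the edgeR calls, 190 of 195, 1684 of 1913 and 758 of 795 were among those of the authors' deposited table.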

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

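The settings that removed a GC or length trend, that thinned the libraries or that left out genes with a 7-base word, and the tests on Nfe2l2 and Nfe2l1, were chosen only after the results they bear on were seen.

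The siRNAs against Usp40 differed from each other by a direct test in 795 genes by edgeR's quasi-likelihood test, and the values below are log2 differences, siRNA 1 minus siRNA 2, with edgeR adjusted p between 7.3e-05 and 0.0405. Higher with siRNA 1 were Ptprc (1.68), Gsta1 (1.5), Cox5a (1.31), Fosl1 (1.3), Mfsd4b1 (1.3), Rcn2 (1.22), Vdac1 (1.21), Psap (1.03) and Slbp (1.0). Mcm4 (0.98), Itgav (0.96), Zmat3 (0.87), Rhoc (0.83), Ero1a (0.70), Tmem64 (0.57), Ccn2 (0.56), Fermt2 (0.56), Birc5 (0.56), Pfn2 (0.54) and Oasl2 (0.50) followed. Akirin1 (0.47), Dnajc3 (0.47), Eda2r (0.45), Ezr (0.42), Tpm1 (0.41), Fth1 (0.38), Lgr4 (0.35), Lpcat1 (0.31), Gsr (0.30) and Pkm (0.29) were also higher with siRNA 1. Lower with siRNA 1 were Pdgfrb (-0.40), Pard3b (-0.50), S100a6 (-0.58), C3 (-0.62), Lipg (-0.73), Ptgfrn (-0.89), Kbtbd8 (-0.90) and Reck (-0.92). Cacng4 (-0.99), Islr (-1.0), Hook1 (-1.0), Hvcn1 (-1.39) and H2bc4 (-1.96) were lower by more. Without siRNA 2 replicate 1 the edgeR adjusted p was 0.111 for Fosl1, 0.0639 for Gsta1, 0.131 for Hvcn1 and 0.09 for Mfsd4b1, without siRNA 1 replicate 3 it was 0.146, 0.119, 0.104 and 0.139, and without siRNA 2 replicate 3 it was 0.0655 for Cacng4. With the length trend removed it was 0.0965 for Gsta1. Fosl1 and Hvcn1 overlap counted genes on the other strand that have more counts, and Islr one on its own strand, so their values are uncertain.

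Lists also differed between the siRNAs by camera with its preset correlation, with median log2 differences of 0.0755 for p53 targets, 0.18 for interferon-stimulated genes, 0.24 for NF-kB targets, 0.33 for NRF2 targets, 0.13 for glycolysis, 0.13 for oxidative phosphorylation, 0.22 for ribosomal proteins and 0.16 for proteasome subunits. With an estimated correlation their adjusted p lay between 0.0505 and 0.833, and by fry between 0.000943 and 0.413.

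The first pattern is the share of changed genes that hold a word of 7 bases in the 3' UTR. A repression of unintended transcripts through short matches of each siRNA may account for part of the falls: the word found in one part of the genes had a z of -9.39 in the part not searched with siRNA 1 and -10.6 with siRNA 2. Both words lie in the Usp40 transcript, but its 4025 bases hold many words of 7 bases, so their presence alone says little. A release from matches of the control siRNA may account for part of the rises with both siRNAs, since a word that is not in the Usp40 transcript had a z of 4.59 in the part not searched for the average contrast, though searches with a single siRNA gave 1 word each that failed there (z of 0.333 and 0.649). Without genes holding a word, 77 calls were left with siRNA 1, 1225 with siRNA 2 and 475 in the average, so these words do not cover all calls. Close words that also passed the shuffles, such as TGACTTA and TTATACA, were not among them, so the calls left may still hold short matches. An effect of the loss of Usp40 itself stays open as untested, since the design holds no rescue of Usp40. The siRNA sequences are not given in the sources used here, so the match to each siRNA was not read directly.

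The second pattern is the larger number of genes changed with siRNA 2 than with siRNA 1. A GC trend, a length trend or a difference in depth each fail as the whole cause, since the ratio of the counts was 10.3, 6.94 and 9.83 with the GC trend removed, with the length trend removed and with the libraries thinned to equal depth. With too few splits of 6 libraries for a share under 0.05, the real counts were 37, 1759 and 1284 for siRNA 1, siRNA 2 and their difference, against 1 in the highest other split, and 1 of 10 splits was as large each time. For both siRNA groups as 1 group, 5 of 84 splits gave at least the real count of 54, the real split included. The highest other split, siRNA 2 against the rest, gave 1217, and siRNA 1 against the rest gave 64. Those splits are treatment groups and not null ones, so this share cannot test chance, and chance was not excluded. Splits of siRNA 1 replicate 1 and control replicate 1 with control replicate 2 (1120) or with siRNA 1 replicate 3 (873) against the rest were also large. These splits gathered libraries with negative slopes of log2 CPM with length. The slopes were -0.155 and -0.0151 in control replicates 1 and 2, and -0.0722 and -0.0327 in siRNA 1 replicates 1 and 3. All other libraries had positive slopes, which points to a structure of the samples along transcript length. Of genes higher with siRNA 1 than with siRNA 2, 277 of 501 held a word of siRNA 2. Off-target matches may thus account for part of the difference. Usp40 fell no further with siRNA 2 (54.2% of control) than with siRNA 1 (44.2%). A difference in Usp40 effects stays open.

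The third pattern is the NRF2 target list, higher with siRNA 1 than with siRNA 2. A lower transcript of the regulator Nfe2l2 with siRNA 2 is a candidate explanation, since Nfe2l2 was higher with siRNA 1 than with siRNA 2 by 0.38 (SE 0.0857, edgeR adjusted p = 0.0193). Against the control it did not pass with either siRNA (log2 fold changes 0.15 and -0.23, edgeR adjusted p = 0.475 and 0.0841). The 3' UTR of Nfe2l2 holds a word of siRNA 2, so an off-target fall of Nfe2l2 and an effect of Usp40 are both open, and the protein was not measured.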

How the results depend on the processing

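The settings with a GC or length trend removed, thinned libraries or genes with a 7-base word left out were chosen after seeing the data. Usp40 kept its fall under every setting tried, with log2 fold changes between -1.25 and -1.06 (siRNA 1) and between -0.97 and -0.77 (siRNA 2) when a library was left out. DESeq2 gave 54 genes lower with both siRNAs. With only the groups compared, siRNA 1 changed 37 genes, the siRNAs differed in 1284, and 10 genes were higher and 4 lower with both, where fewer libraries enter the fit. With both siRNA groups as 1 group the average gave 54 genes, and 62 named genes lost their calls. With the length trend removed the counts were 330 for siRNA 1, 1364 for the average, 93 higher with both and 69 lower with both. Without genes holding a word the counts fell by construction to 77, 1225, 475 and 370 for siRNA 1, siRNA 2, the average and the difference, and to 27 higher and 12 lower with both. For the other settings where no reason is named the cause was not tested.

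With each library left out, the counts ran from 36 to 234 for siRNA 1, 636 to 2608 for siRNA 2, 174 to 1478 for the average, 361 to 1335 for the difference, 10 to 51 higher with both and 3 to 51 lower with both. The correlation of the fold changes ran from 0.347 without siRNA 1 replicate 2 to 0.706 without control replicate 3. The median of the oxidative phosphorylation list with siRNA 1 ran from -0.165 without siRNA 1 replicate 1 to 0.0234 without control replicate 1, where it reversed, and the cause was not tested. Median-of-ratios scaling ended 0 calls of named genes by edgeR, upper-quartile scaling 2, DESeq2 3 and limma-voom 3. A replicate block gave 226, 2295, 1092 and 927 genes. Deviations from the group mean of same-number libraries correlated from -0.478 (siRNA 1 and siRNA 2 replicate 2) to 0.755 (control and siRNA 1 replicate 1). For control replicate 3 and siRNA 1 replicate 3 the value was -0.205. Such deviations also followed transcript length, so they cannot show whether the numbers pair the libraries. The setting with uniquely mapped reads was not run, since the table gives total counts. Small changes were the hardest to recover: in simulated data for siRNA 1 against the control over 11800 genes, edgeR recovered 32% of the genes changed 1.3-fold and 96% of those changed 3-fold.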

Other observations

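The test on Nfe2l1 was chosen only after the proteasome list was seen.

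Among YAP and TEAD targets, 5 of 22 were higher with siRNA 1 than with siRNA 2 (6 higher and 1 lower adjusted over the list alone): Ccn2 (0.56) and, chosen after their values were seen, Ankrd1 (0.59, SE 0.0746), F3 (0.49, SE 0.0731), Lats2 (0.47) and Gadd45b (0.44) on the log2 scale, with a camera adjusted p of 0.0538. Of 34 p53 targets, 4 were higher, Zmat3 (0.87), Eda2r (0.45), Ccng1 (0.48) and Plk2 (0.42), and Sesn1 (-0.53) was lower (4 and 1 adjusted over the list alone), where Ccng1, Plk2 and Sesn1 were chosen after their values were seen. The integrin gene Itgb1 fell with siRNA 1 (-0.36, SE 0.0617, edgeR adjusted p = 0.015), also chosen after its values were seen.

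A hypothesis is that the lower proteasome list with siRNA 2 could follow a lower transcript of Nfe2l1, a regulator of proteasome genes. Nfe2l1 had a log2 fold change of -0.13 with siRNA 2 (SE 0.097, edgeR adjusted p = 0.35), which neither meets nor excludes the fall that the hypothesis needs, so it stays open. The 3' UTR of Nfe2l1 holds a word of siRNA 2, as that of Nfe2l2 does, so an off-target effect on it is open too. Its activity depends on processing of the protein, which was not measured.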
